A study of Mus musculus with 2 samples.

How the data were processed

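Haematopoietic stem and progenitor cells of mouse bone marrow were profiled in 2 libraries, 1 labelled control and 1 labelled OP-HU, each of cells enriched by lineage depletion and CD117 beads and captured on a high-density GEXSCOPE microwell chip (Singleron), per the labels' protocols. The group of each library was taken from its condition label, and how many animals gave each library is not given in the sources used here. The deposited values are raw counts, whole numbers of UMIs per gene and cell, per the file headers, with Ensembl gene IDs and symbols. The genome build mm10 and Scanpy 1.8.1 are named, with no role, per the submitters' processing notes. The aligner, the counting tool, the gene annotation and the rule that called cells are not given in the sources used here. The barcodes had been reduced to called cells before deposit, since the shallowest barcode held 1121 UMIs in the control library and 675 in the OP-HU library. Of the control barcodes, 1428 (3.01%) also occurred in the OP-HU library, and these were treated as separate cells. Both libraries list 32589 genes, of which 24546 and 24773 had at least 1 UMI. Coordinates, transcript lengths and GC content came from the GENCODE M21 annotation and the GRCm38 sequence, which matched 32522 (99.8%) of the gene IDs, 97.1% of them with the same symbol. Histone genes with older symbols in the lists were matched through their IDs, and 52 symbols occur on more than 1 ID.

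Depth was 273555759 UMIs in 47470 control cells and 313417195 UMIs in 53667 OP-HU cells. The middle 90% of cells lay between 1455.45 and 13650.5 UMIs in the control library and between 1023 and 14173.7 in the OP-HU library. Cells were kept with at least 500 genes and at most 20% mitochondrial UMIs. This left out 141 control and 409 OP-HU cells for their gene number and none for mitochondrial UMIs, whose highest share was 11.0% and 19.6%. Doublets were called in each library with scrublet in scanpy 1.11.5 (expected rate 0.08, 1 simulated doublet per cell, exact neighbours) and left out. The caller marked 2817 control cells (5.94%) and 5914 OP-HU cells (11.0%), with median depths of 8351 and 8773.5 UMIs, and placed 40.5% and 60.0% of the simulated doublets above its thresholds, so some doublets remain. The cells kept were 44512 and 47348, with 246687106 and 256476030 UMIs.

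The cells of both libraries were clustered together with no batch correction. Counts were scaled to the total of each cell and log-transformed, 2000 variable genes were chosen over the libraries, each gene was scaled with values clipped at 10 SD, and 30 exact principal components, 15 neighbours weighted by shared neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0) gave the clusters. Genes were ranked in each cluster by fold over the other cells of the same library among genes with a UMI in at least 10% of the cluster. A cluster took the name of the marker list with most members among its top 50 genes, if at least 3 were there, at least 1 was among the top 10, and no other list had more in the top 10. Other clusters stayed unnamed. Early erythroid and haemoglobin clusters together form the erythroid class. No deposited cell annotation was used. Main classes are the 6 with at least 5% of cells in a library, and 8 classes with at least 200 cells in each library were compared for expression.

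UMIs were summed over all cells, or over the cells of a class, in each library and divided by that total to give counts per 1000000 UMIs (CPM). With 1 library per group there is no test between conditions, no p-value and no standard error. Each summed count and each share of UMIs has an exact Poisson interval, each share of cells an exact Clopper-Pearson binomial interval, and each ratio of CPM an exact conditional binomial interval, at 95%. The interval of a ratio of shares uses the normal approximation on the log scale. Ratios with class makeup held equal or from the mean over cells keep the interval width of the plain sums, which leaves the weighting out. All of them cover counting error only. A count of 0 enters a ratio as 3 counts over the library or class. Ratios are OP-HU over control on the log2 scale. The size rule counts genes with at least 10 CPM in at least 1 library and a log2 ratio of at least 1 in size. A list is described by the median log2 ratio of members with at least 5 CPM in at least 1 library, by members whose ratio is 0.32 or more in size (1.25-fold) with an interval that leaves out 0, and by the percentile of its median among 10000 random lists of the same size, each member drawn from a window of 201 genes of like expression. These 43 lists, 15 of cell type markers and 28 of pathways and complexes, and the size rule, the rule for named genes and the first set of alternatives were fixed before the data were examined. Genes were named by this rule: over all cells Brd4 and the 10 largest and 10 smallest ratios meeting the size rule, in each main class the 5 largest and 5 smallest at 50 CPM or more and Brd4, and up to 4 members with the largest absolute ratio of each list, leaving out gene models named Gm with a digit, ending in Rik, holding -ps or beginning with AC, AL, BC or CT and digits. Other genes that are named, such as the ribosomal RNA-linked genes, Kit, Mpo, Malat1 and Neat1, were chosen after their values were seen.

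For cell cycle phases and genes per cell, each cell was thinned at random to 2000 UMIs, the largest of the sizes tried that kept at least 80% of each library (86.9% and 81.8% were kept). Phases came from the S and G2 and M lists with scanpy. Trends of log2 ratio on GC content, transcript length and gene span were fitted as cubic polynomials. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9 were used, with random seed 0.

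The calculation was tested on simulated Poisson counts drawn from the pooled means and the totals of the real libraries with 200 changed genes per comparison. The intervals rest on the same model, so their coverage checks the calculation and not the spread between cells or libraries, which the simulation leaves out. Over all cells (8540 genes) the size rule took 100 of 100 genes changed by 1.5 on the log2 scale, 0 of 100 changed by 0.5 and 0 unchanged genes. Intervals held the true ratio for 95.4% of genes. Of 200 lists drawn at random, which could hold changed genes, 13 lay outside the middle 95% of random lists. In the erythroid class (7898 genes) the size rule took 100 of 100, 0 and 0, with 95.0% coverage and 9 of 200 lists outside. In the megakaryocyte class (8876 genes) it took 99 of 100, 0 and 0, with 95.2% coverage and 4 of 200 lists outside. A list shifted on purpose reached percentile 100 in each of these.

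Alternatives for cells were a looser filter (200 genes), a stricter one (1000 genes and 10% mitochondrial UMIs) and doublets kept. Those for classes were resolutions 0.5 and 2, components centred within each library, 951 genes left out before clustering (cell cycle, ribosomal, mitochondrial, haemoglobin and size-rule genes) and thinned cells. Those for levels were median-of-ratios factors, the TMM factor of edgeR 4.0.16 (R 4.3.3), totals without haemoglobin, ribosomal protein and mitochondrial genes and the 20 genes with most UMIs, the mean of each cell's own CPM, and the makeup of classes held equal (class CPM weighted by the mean share of the class in the 2 libraries, over classes with at least 20 cells in each). Further ones were floors of 1 and 50 CPM, lists with no floor, values within each class, and phases without thinning. Chosen after seeing the data were a common floor of 1121 UMIs per cell, each library clustered on its own, and class labels passed from the 15 nearest cells of the other library. A batch correction by an integration tool was left out, because library and condition are the same split and a correction would remove both.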

Results

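Single-cell RNA profiles were collected from haematopoietic stem and progenitor cells of C57 BL/6 mouse bone marrow (femur and tibia) at 12 weeks of age. Red cells were lysed, and the remaining cells were enriched by lineage depletion and by magnetic beads against CD117, the stem cell factor receptor Kit that most early blood progenitors carry. The design holds 2 groups with 1 library each, a control library and a library labelled OP-HU. The labels of the samples do not expand this name, and the series title speaks of mice with disuse osteoporosis, bone loss that follows reduced loading. For each library 90000 cells were loaded on a microwell chip built to capture 20000 to 50000 cells. The control library held 47470 cells with 273555759 UMIs (unique molecular identifiers, each standing for 1 captured transcript), and the OP-HU library held 53667 cells with 313417195 UMIs. Median depth was 4739.5 UMIs and 2313 genes per cell in the control library, and 4839 UMIs and 2391 genes in the OP-HU library. The shallowest cell had 1121 UMIs in the control library and 675 in the OP-HU library. After removal of cells with few genes and of marked doublets, 44512 control cells and 47348 OP-HU cells were compared, with medians of 4588 and 4553 UMIs. With 1 library per condition, each difference between the libraries has no replicate check, no test between conditions can be made, and intervals (95%) cover counting error only.

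The first comparison asked how the makeup of the enriched marrow differed between the libraries, since the series title names a myeloid bias. Erythroid-like cells made up 7.31% (7.07 to 7.56) of control cells and 27.0% (26.6 to 27.4) of OP-HU cells, a share 3.69-fold higher in the OP-HU library (log2 ratio 1.88, 1.83 to 1.94). Neutrophil progenitor-like cells, which make the primary granule proteases, made up 50.1% (49.6 to 50.5) of control cells and 21.1% (20.8 to 21.5) of OP-HU cells, a share 2.37-fold lower in the OP-HU library (log2 ratio -1.25, -1.27 to -1.22). Late neutrophil-like cells, which carry the secondary granule genes, were 7.08% and 8.41% (log2 ratio 0.25, and -2.43 to 0.91 in the alternatives). Both neutrophil classes together, a sum added after the data were seen, were 57.1% of control cells and 29.5% of OP-HU cells (log2 ratio -0.95). With each library clustered on its own, both together were 28.9% and 28.3% (-0.03, with 38.5% of control cells unnamed), and the ratio was -0.32 with doublets kept and -0.61 with the looser filter. Monocyte progenitor-like cells were 18.1% and 15.2% (log2 ratio -0.26, but -0.03 in thinned cells and -0.01 with each library clustered on its own), and haematopoietic stem cell (HSC) and multipotent progenitor-like cells were 9.83% and 13.5% (log2 ratio 0.46, and 0.36 to 0.96 in the alternatives that gave a value, with no control cells in this class when each library was clustered on its own). All classes are named from marker genes, and "like" is left out from here on.

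Smaller classes also took different shares of the libraries. Megakaryocyte cells, the platelet lineage, were 2.55% of control cells and 6.99% of OP-HU cells (log2 ratio 1.46, and -0.27 to 1.46 in the alternatives). Basophil and mast cells were 1.54% and 3.14% (log2 ratio 1.02), and eosinophil cells 1.55% and 2.32% (0.58). A B lineage class led by immunoglobulin transcripts was 0.993% and 0.384% (-1.37). Dendritic cells were 0.175% and 0.444% (1.34). T, NK and innate lymphoid cells were 13 of the control cells (0.0292%) and 150 of the OP-HU cells (0.317%). The share ratio of eosinophil cells was -0.08 (-0.23 to 0.07) with a common UMI floor and 0.13 (-0.08 to 0.34) in thinned cells, and that of dendritic cells 0.18 (-0.25 to 0.61) with classes passed from the control library. The stricter filter gave -0.34 for the B lineage and 2.03 for basophil and mast cells. Cells of unnamed clusters were 0.789% and 1.23%.

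**Figure D1:**
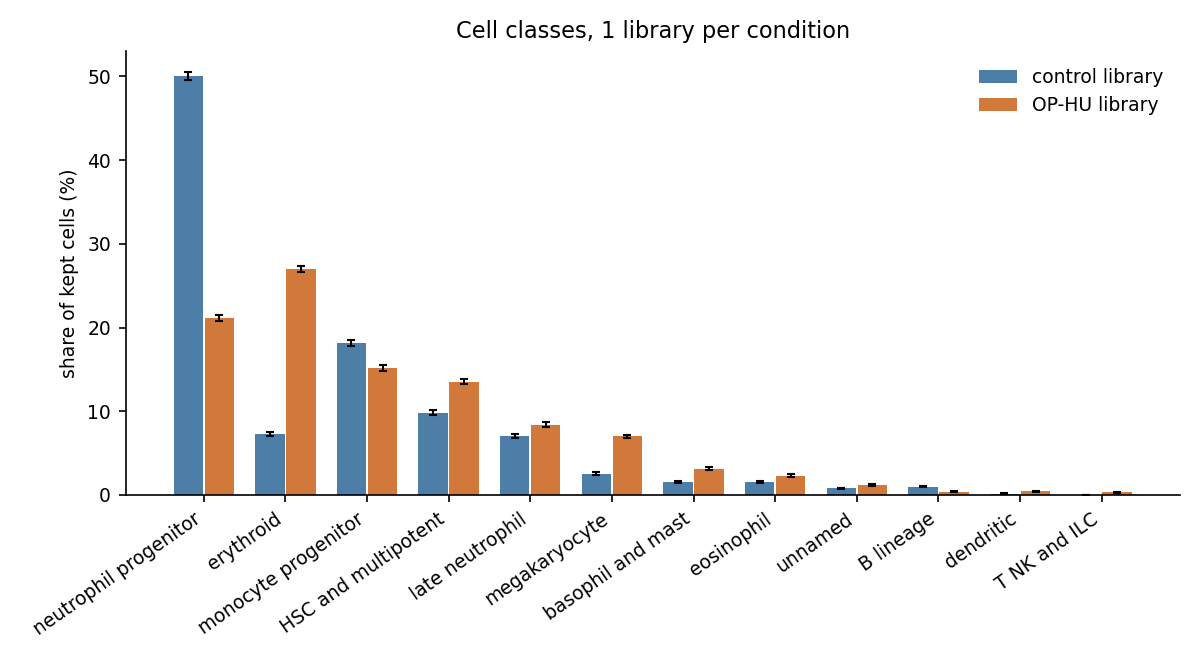
Share of kept cells (%, vertical axis) in each cell class (horizontal axis) for the control library (blue) and the OP-HU library (orange). Bars are shares of 44512 and 47348 cells, and error bars are exact 95% binomial intervals that cover counting error only. Erythroid cells stand at 7.31% and 27.0%, and neutrophil progenitors at 50.1% and 21.1%.

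Within the erythroid class, clusters named for each stage held a larger share of cells in the OP-HU library. Clusters led by early erythroid markers held 6.81% of control cells and 19.2% of OP-HU cells, 2.81-fold higher (log2 ratio 1.49, 1.44 to 1.55). Clusters led by haemoglobin and late erythroid markers held 0.501% and 7.83%, 15.6-fold higher (log2 ratio 3.97). Late clusters were 6.85% of the erythroid cells of the control library and 29.0% of those of the OP-HU library. Over the whole erythroid class, however, haemoglobin genes took 0.240% of control UMIs and 0.184% of OP-HU UMIs (log2 ratio -0.38). Late erythroid markers had a median log2 ratio of -0.34 in that class. Different clusters held most erythroid cells of each library, so the names early and late may not mark the same stage in both. Kit, the gene of the antigen used for the enrichment, stood at 362 counts per 1000000 UMIs (CPM) in the early erythroid clusters of the control library and at 215 CPM in those of the OP-HU library (log2 ratio -0.75), and at 59.7 and 92.3 CPM in the late clusters (0.63, 0.25 to 1.04). Over all cells Kit stood at 221 and 176 CPM (-0.33). A cluster of late neutrophil cells led by Retnlg, Mmp8 and Mmp9, genes of mature neutrophils, held 0.773% of control cells and 3.29% of OP-HU cells. Lineage depletion and the CD117 beads act on each of these shares, and the OP-HU library holds more cells than the upper end of the capture range of the chip.

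Clusters separated the libraries, so a cluster that is mostly 1 library may be that library and not a cell type. Neutrophil progenitors came from clusters 0 and 3 in the control library (13621 and 8575 cells, against 106 and 62 OP-HU cells) and from cluster 1 in the OP-HU library (9832 cells, against 89). Erythroid cells came mainly from cluster 10 in the control library (2905 cells) and clusters 2 and 8 in the OP-HU library (8939 and 3171 cells). Monocyte progenitors came mainly from clusters 4 and 6, HSC and multipotent cells from clusters 7 and 5, and megakaryocyte cells from clusters 16 and 9, in that order of control and OP-HU. Late neutrophils came mainly from cluster 11 in the control library and clusters 12 and 14 in the OP-HU library. When the genes of the size rule (2-fold or more, described with the expression comparison), cell cycle, ribosomal, mitochondrial and haemoglobin genes were left out before clustering, the log2 share ratios were 1.96 for erythroid cells, -1.15 for neutrophil progenitors, -0.19 for monocyte progenitors, 0.71 for HSC and multipotent cells, 0.36 for late neutrophils and 0.28 for megakaryocyte cells. Each library clustered on its own gave -0.28 for neutrophil progenitors, with 38.5% of control cells then unnamed. The direction for late neutrophils reversed in 3 alternatives (-2.43 to -1.14) and that for megakaryocyte cells in 5 (-0.27 to -0.05).

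**Figure D2:**
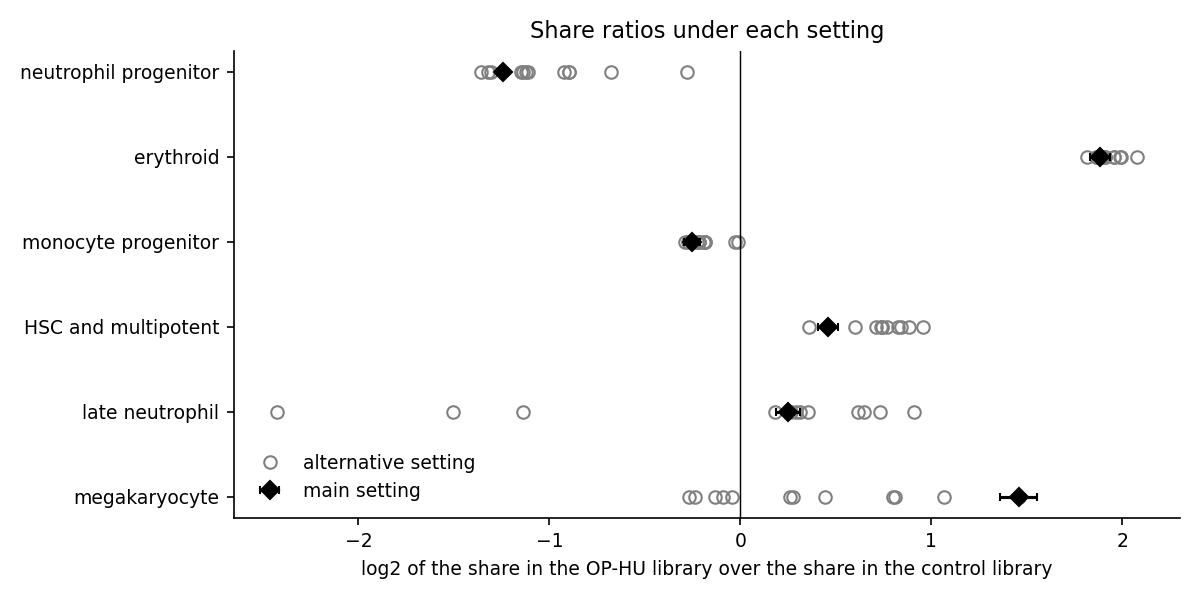
Log2 of the share of a class in the OP-HU library over its share in the control library (horizontal axis) for the 6 main classes (vertical axis). Black diamonds are the main setting with its 95% counting interval, and grey circles are alternative settings. Erythroid values lie between 1.82 and 2.08, neutrophil progenitor values between -1.36 and -0.28, and values of late neutrophils and megakaryocyte cells lie on both sides of 0.

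The second comparison concerned Brd4, the bromodomain protein that reads acetylated chromatin and is named in the series title. The gene (chromosome 17, 32196274 to 32284722, minus strand, GRCm38) stood at 142 CPM in the control library (141 to 144) and 222 CPM in the OP-HU library (220 to 224), 1.56-fold higher (log2 ratio 0.65, 0.63 to 0.66). Brd4 was higher in the OP-HU library in each of the 8 classes compared. Its log2 ratio was 0.69 in HSC and multipotent cells, 0.69 in neutrophil progenitors, 0.63 in monocyte progenitors, 0.57 in late neutrophils, 0.44 in erythroid cells, 0.71 in megakaryocyte cells, 0.70 in basophil and mast cells and 0.54 in eosinophil cells. Brd3, a paralog in the same family, was higher by a similar ratio over all cells (129 and 201 CPM, 0.64) and by 0.43 to 0.75 across classes. Brd2 stood at 265 and 316 CPM (0.26; 0.08 to 0.42 across classes), and Brdt, a germ cell gene, near 1 CPM in both libraries (1.13 and 0.893).

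Many genes of like expression differed as much as Brd4 did. Among the 1000 genes nearest to it in expression, the log2 ratio of Brd4 lay at percentile 85.9 over all cells and at percentiles 75.0 to 92.5 within classes. The ratio over all cells was 0.63 with the makeup of classes held equal (0.61 to 0.64, an interval with the width of the plain sums that leaves the weighting out). No alternative moved the ratio over all cells outside 0.60 to 0.69.

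**Figure D3:**
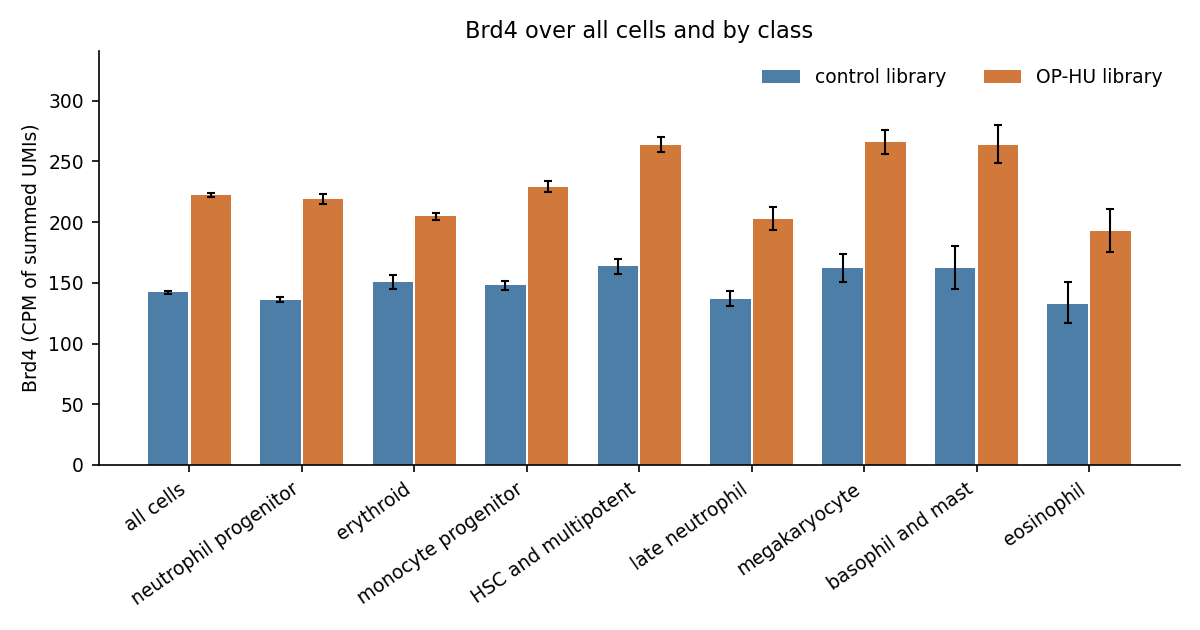
Brd4 level in counts per 1000000 of the UMIs summed over all cells or over 1 class (vertical axis) in the control library (blue) and the OP-HU library (orange), over all cells and in each of 8 classes (horizontal axis). Error bars are exact 95% Poisson intervals (counting error only). Levels over all cells are 142 and 222 CPM, and the OP-HU bar is the higher one in each class.

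The third comparison described expression over all cells. Of 8759 genes at 10 CPM or more in at least 1 library, 443 were 2-fold or more higher in the OP-HU library and 320 were 2-fold or more lower, 8.71% of these genes. This is a rule of size for 2 libraries and not a count of tested changes. With each cell given the same weight, 433 genes were higher and 193 lower. With the makeup of classes held equal, 176 were higher and 105 lower, and 212 of the 763 genes were shared with the main count.

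Among the 10 genes with the largest ratios, Klf1, the master transcription factor of red cell development (chromosome 8, 84901928 to 84905291), stood at 17.3 and 125 CPM (2.86), and the erythroid gene Tspan33 at 18.7 and 123 CPM (2.72). The largest ratio was that of Podxl (chromosome 6, 31519488 to 31563981), a sialomucin of progenitor cells, at 0.454 and 11.3 CPM (log2 ratio 4.63, 4.36 to 4.92). Lmna, the gene of nuclear lamin A, stood at 13.5 and 123 CPM (3.19). Sfrp4 (3.46), Phlda2 (3.13), Reep6 (2.78) and Bex4 (2.72) followed, together with the mitochondrial genes mt-Nd5 (3.38) and mt-Nd3 (2.90). The 10 smallest ratios included Camk1d (336 and 14.6 CPM, -4.52), Lars2 (836 and 45.5, -4.20), Cmss1 (1333 and 112, -3.57) and AY036118 (285 and 6.04, -5.56), which moved together with ribosomal RNA-linked genes treated separately here. The immunoglobulin heavy chain genes Ighg1 (283 and 18.1 CPM, -3.96) and Ighg2c (202 and 21.0, -3.26), products of plasma cells, were also among them. Ighg1 stood at 51.6 and 2.18 CPM within monocyte progenitors, a class that makes no immunoglobulin, and the B lineage class was 0.993% and 0.384% of cells. Rhoj (-3.87), Degs2 (-2.96), Arap1 (-2.77) and Clu (-2.75) completed the list.

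Erythroid and primary granule marker lists moved as the shares of their classes did, and several other marker lists did not. Clusters were named from these same lists, so list values and class shares are not independent. Of 17 measured early erythroid markers, 16 were higher, 0 lower and 1 neither (median log2 ratio 2.05, 1.50 to 2.25; percentile 100 among 10000 random lists matched on expression), including Klf1, Blvrb (2.55), Car2 (2.38) and Cldn13 (2.32). Of 15 haemoglobin and late erythroid markers, 13 were higher (median 1.80, percentile 100), including Trim10 (2.40), Hbb-bs (2.33) and Gypa (2.32). Adult haemoglobin genes come in near-identical pairs, and how counts were divided between them is not given in the sources used here. Of 16 neutrophil primary granule markers, 0 were higher and 13 lower (median -0.76, percentile 0), including Prtn3 (9497 and 2650 CPM, -1.84), Ms4a3 (-1.40), Alas1 (-1.31) and Srgn (-1.11). Late granule markers had 11 of 17 higher and 4 lower (median 0.55, percentile 99.9), with Lyz2 (1.73) and Retnlg (1.72) in front. Basophil and mast markers had 8 of 11 higher (median 0.84), among them Cpa3 (1.75) and Prss34 (1.44), and eosinophil markers 4 of 5 (median 0.49). Megakaryocyte markers had 4 of 12 higher and 6 lower (median -0.31, percentile 2.01), with Fli1 at -0.89 and Itgb3 at -0.88. The share ratio of the class itself was 1.46 and reversed in 5 alternatives. HSC markers (median 0.04, 5 higher and 3 lower of 16), monocyte markers (-0.03, 3 and 6 of 17), lymphoid progenitor markers (0.06, 4 and 1 of 10) and dendritic markers (0.15, 2 and 1 of 6) lay near the middle. With the makeup of classes held equal, the median was 0.09 for early erythroid markers, -0.13 for late erythroid markers, 0.00 for primary granule markers and -0.05 for basophil and mast markers.

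**Figure D4:**
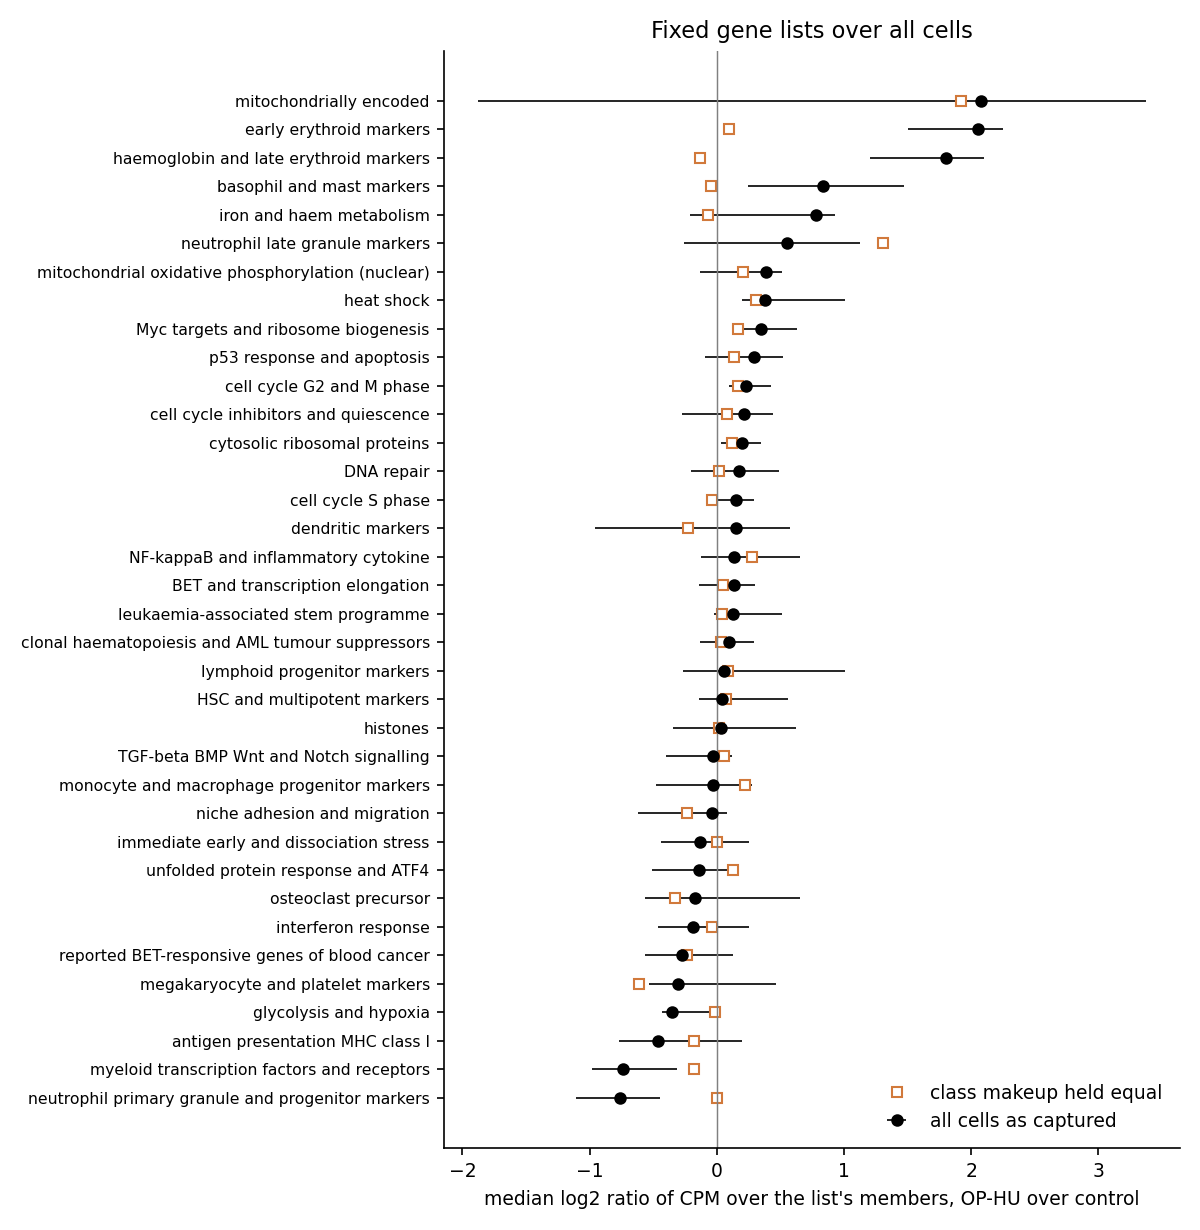
Median log2 ratio of CPM over the members of each fixed gene list (horizontal axis, OP-HU over control) for lists with at least 6 measured members (vertical axis). Black points are all cells as captured with the 95% interval of the median over members, and orange squares are the value with the makeup of classes held equal. Early erythroid markers stand at 2.05 and 0.09, primary granule markers at -0.76 and 0.00, and the mitochondrially encoded list at 2.08 and 1.92.

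Lists were also fixed for the leukaemic and BET themes of the series title. Of 22 measured genes reported to respond to BET proteins (the family of Brd4) in blood cancer, 4 were higher and 11 lower (median -0.27, -0.56 to 0.13; percentile 0.48). Members that differed most were Gfi1, a repressor needed for neutrophil formation (222 and 68.7 CPM, -1.69), the erythroid and stem cell factor Tal1 (1.50), the survival gene Bcl2l1 (-1.28) and Fli1. Leukaemia-associated stem programme genes had 9 of 28 higher and 5 lower (median 0.13, -0.02 to 0.51; percentile 73.7), with Hmga2 (1.33 and 7.51 CPM, 2.49), Trib2 (1.91), Sox4 (0.92) and Pbx3 (0.73) in front. Clonal haematopoiesis and leukaemia suppressor genes had 7 of 25 higher and 6 lower (median 0.09, percentile 60.7), among them Ezh2, a histone methyltransferase (1.06), Npm1 (0.82), Cebpa (-0.98) and Idh1 (-0.73). BET and transcription elongation genes had 9 of 30 higher and 7 lower (median 0.14, percentile 79.3), with Med12 at 17.6 and 2.64 CPM (-2.74), Supt4a at 1.49, Cdk8 at -1.17 and Ell2 at 1.03. Med12, Supt4a and Cdk8 differed by 2-fold or more in each of the 6 main classes. Myeloid transcription factors and receptors had 3 of 23 higher and 16 lower (median -0.74, -0.98 to -0.31; percentile 0), including Gfi1, Id2 (-1.26), Hck (-1.18) and Il3ra (-1.08). With the makeup of classes held equal, the myeloid median was -0.18 and that of BET-responsive genes -0.24.

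Growth, metabolic and stress lists leaned in both directions. Myc targets and ribosome biogenesis genes had 16 of 28 higher and 2 lower (median 0.35, percentile 99.6), with Nop58 (0.98), Gnl3 (0.98) and Nolc1 (0.95) against Fbl (-0.92). Nuclear genes of oxidative phosphorylation had 15 of 27 higher and 2 lower (median 0.39, percentile 99.7), including Atp5j (1.74) and Ndufa4 (1.07). Iron and haem metabolism genes had 12 of 18 higher and 2 lower (median 0.78), among them Steap3 (1.55), Cpox (1.49) and the ferritin gene Fth1 (1.47), against -0.07 with the makeup of classes held equal. Glycolysis and hypoxia genes had 3 of 23 higher and 13 lower (median -0.35, percentile 0.11), led by Pgam1 (-1.26), Egln3 (-1.05) and Pfkp (-0.84), and stood at -0.02 with makeup held equal. Heat shock genes had 8 of 13 higher and 0 lower (median 0.38, percentile 96.3), including Hsph1 (1.82) and Hsp90aa1 (1.04). Genes of p53 response and apoptosis had 10 of 20 higher and 5 lower (median 0.30), with Casp3 at 78.2 and 337 CPM (2.11) and Pmaip1 at -1.51. Cytosolic ribosomal protein genes had 36 of 87 higher and 19 lower (median 0.20, percentile 98.3). Rps27rt (1.74) in that list is close in sequence to Rps27 and therefore uncertain, Rpl36 (1.48) followed, and Rps6ka3 (-1.30) is a kinase that the symbol rule took in. The list was built from the form of the symbols, so its counts are not of ribosomal proteins alone.

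Immune, signalling and niche lists were described in the same way. MHC class I genes had 0 of 11 higher and 6 lower (median -0.46, percentile 0.27), with the peptide transporter Tap2 (-0.79) and H2-K1 (-0.47). Interferon response genes had 2 of 12 higher and 5 lower (-0.18), with Ifi203 (1.20) and Bst2 (-0.96). MHC class II genes had 1 of 4 higher and 1 lower (0.20). NF-kappaB and cytokine genes had 8 of 26 higher and 6 lower (0.14), with Il6 (2.17) and Il1b (1.05) against Tnfrsf1b (-1.61) and Tlr4 (-1.51). Immediate early genes had 5 of 21 higher and 9 lower (-0.13), including Atf3 (1.55) and Klf2 (-1.12). Unfolded protein response genes had 4 of 22 higher and 7 lower (-0.14), with Asns (1.47) and Xbp1 (-0.95). Niche adhesion and migration genes had 1 of 19 higher and 9 lower (-0.04), among them Vcam1 (74.2 and 22.4 CPM, -1.73), Sell (-0.87) and the homing receptor Cxcr4 (-0.63). Osteoclast precursor genes had 2 of 9 higher and 3 lower (-0.17), with Mmp9 (1.12) and Csf1r (-0.56). TGF-beta, BMP, Wnt and Notch genes had 3 of 18 higher and 6 lower (-0.03), with the Notch target Hes1 at 2.15 and Id1 at -1.54. DNA repair genes had 10 of 26 higher and 2 lower (0.18), with Xrcc5 (1.18) and Xpc (-0.95), and histone genes 7 of 17 higher and 5 lower (0.03), with H1f5 (1.47) and H1f0 (-1.11). Markers of further cell types gave few measured members. B lineage markers had 3 of 5 higher and 2 lower (Ighm 2.30, Iglc2 -1.07), macrophage markers 0 of 2 higher and 1 lower (Vcam1), T and NK markers had 1 measured gene (Nkg7, -0.69, shared with the primary granule list), and stromal and endothelial markers had 0. Of 4 measured sex-linked genes, 1 was lower (Eif2s3y, -0.44) and 3 were neither.

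The fourth comparison was made within cell classes, where differing shares weigh less, although different clusters held most of each main class in the 2 libraries (named with the shares). By the rule of size, 202 genes were higher and 103 lower in neutrophil progenitors (clusters 0 and 3 against cluster 1), 175 and 86 in monocyte progenitors (clusters 4 and 6), 205 and 143 in HSC and multipotent cells (clusters 7 and 5), 190 and 373 in erythroid cells (cluster 10 against clusters 2 and 8), 404 and 400 in megakaryocyte cells (clusters 16 and 9) and 492 and 573 in late neutrophils (cluster 11 against clusters 12 and 14). Basophil and mast cells had 343 and 274, and eosinophil cells 461 and 205. Of the control HSC and multipotent cells, 71.3% kept that class when classes were passed from the OP-HU library. No control cell was named so when each library was clustered on its own. Values within HSC and multipotent cells may therefore compare different stages. Of the 443 genes higher over all cells, 139 met the rule in none of the 6 main classes and 33 in each of them. Of the 320 lower genes the counts were 63 and 28. Genes that met the rule in each main class include the list members Med12, Cdk8, Supt4a, Atp5j, Rps27rt, H1f5 and Kif20b. Mitochondrial and ribosomal RNA-linked genes are among them too. A shift shared by all main classes cannot be told apart from a difference between the libraries.

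The same few genes led most classes. AY036118, Camk1d, Lars2 and Cmss1 were among the 5 smallest ratios in each main class, and mt-Nd5 among the 5 largest in each main class except late neutrophils. Beyond these, Ighm (10.2 and 69.1 CPM, 2.77) and the phosphodiesterase gene Pde4b (7.77 and 51.6 CPM, 2.73) led in neutrophil progenitors. Ighm stood at 70.1 and 346 CPM over all cells, and without a measured background its UMIs are not read as expression in that class. Pde4b was also higher in HSC and multipotent cells (46.3 and 223 CPM, 2.27) and in monocyte progenitors (2.55). In erythroid cells, UMIs of the neutrophil protease gene Prtn3 stood at 1093 and 200 CPM (-2.45), against 9497 and 2650 CPM over all cells, and no background of free RNA was measured, so expression in these cells is not read from it. Slc25a5, the mitochondrial ADP/ATP carrier, was higher (407 and 1718 CPM, 2.08). In late neutrophils, Thbs1, the gene of thrombospondin 1 (5.96 and 187 CPM, 4.97), Lyz2, lysozyme (574 and 4725 CPM, 3.04), and the chemokine gene Ccl6 (2.85) were higher, and Lipg was lower (-3.52). The primary granule genes Mpo (9587 and 2983 CPM) and Prtn3 (9802 and 1790 CPM) were lower in the OP-HU cells of this class. When classes were passed from the OP-HU library, 75.8% of its control cells kept it, so values within late neutrophils may compare different stages. In megakaryocyte cells, the erythroid genes Klf1 (3.06) and Car1 (117 and 848 CPM, 2.86) and the stem cell gene Ifitm1 (2.97) were higher, Arap1 was lower (-3.28), and all 19 measured megakaryocyte markers were lower (median -1.27). When classes were passed from the control library, 35.3% of the OP-HU cells of this class kept it and the share was 2.47% in place of 6.99%, so values within it may compare different cell types.

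UMIs of erythroid and primary granule markers also differed within other classes. No background of free RNA was measured, so expression of these markers in cells of another lineage is not read from the values. Early erythroid markers had medians of 1.34 in neutrophil progenitors, 1.31 in monocyte progenitors, 0.85 in HSC and multipotent cells and 1.75 in late neutrophils, against -0.20 in erythroid cells themselves. Hbb-bs, a haemoglobin gene, stood at 4.33 and 17.5 CPM in neutrophil progenitors. Primary granule markers had a median of -1.31 in erythroid cells and -1.50 in megakaryocyte cells, against 0.21 in neutrophil progenitors. Basophil and mast markers had medians of -0.52 in HSC and multipotent cells and -0.71 in erythroid cells, and megakaryocyte markers -0.31 and -0.63. Mpo, the neutrophil peroxidase gene, stood at 1871 and 577 CPM in erythroid cells and at 15180 and 17689 CPM in neutrophil progenitors. Myeloid transcription factors and receptors had 0 of 19 higher and 17 lower in erythroid cells (median -1.23), 4 of 22 higher and 8 lower in neutrophil progenitors (-0.19), 3 of 23 and 7 in monocyte progenitors (-0.12), 4 of 23 and 12 in HSC and multipotent cells (-0.32), and 8 of 23 and 6 in late neutrophils (0.13). BET-responsive genes had a median of -0.57 in erythroid cells and -0.16 in HSC and multipotent cells, and leukaemia-associated stem programme genes -0.27 and 0.03.

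A further contrast between the libraries lay in ribosomal RNA-linked and mitochondrial UMIs. A set of 8 genes chosen after the data were seen (Gm42418, AY036118, Gm26917, Gm15564, Gm19951, Lars2, Camk1d and Cmss1), of which Gm42418 and AY036118 lie over ribosomal RNA sequence, took 2.74% of control UMIs and 0.189% of OP-HU UMIs, 14.5-fold lower in the OP-HU library. Across the 8 classes the log2 ratio of this sum lay between -4.54 and -3.45. Gm42418 alone took 2.42% of control UMIs and 0.166% of OP-HU UMIs. Over all cells the log2 ratios of the single genes ran from -5.56 (AY036118) to -2.61 (Gm26917). Transcripts of the 13 mitochondrially encoded genes took 0.196% and 0.710% of UMIs, 3.63-fold higher in the OP-HU library, and 0.83 to 1.82 higher on the log2 scale across classes. Of the 8 measured mitochondrial genes, 7 were higher and 1 lower (median 2.08). mt-Nd2 (2.49) and mt-Cytb (2.11) were among the higher ones, and the lower one, mt-Nd6 (-1.88), is the gene encoded on the opposite strand from the rest. Haemoglobin genes took 0.0185% and 0.0753% of UMIs, and cytosolic ribosomal proteins 8.66% and 8.98%. Of the nuclear-retained RNAs, Malat1 stood at 1082 and 1832 CPM and Neat1 at 126 and 59.9 CPM, both picked after their values were seen.

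**Figure D5:**
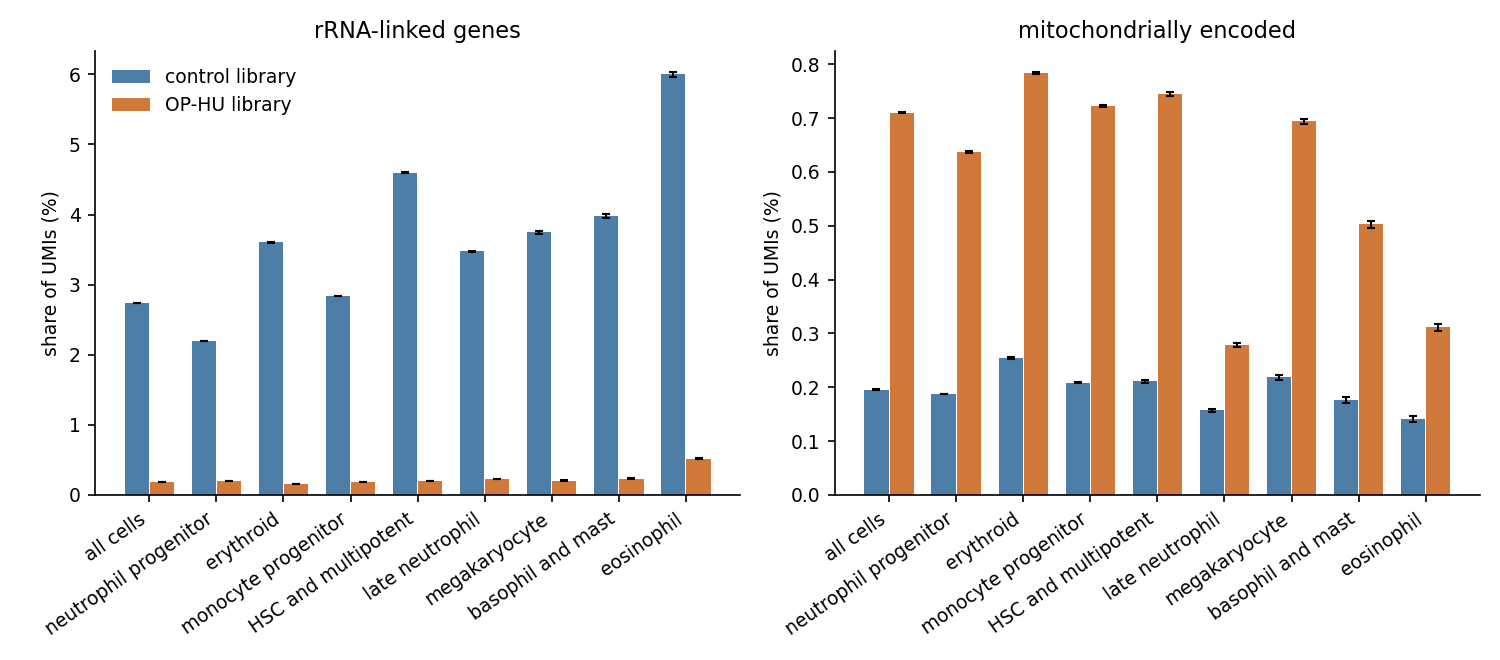
Share of UMIs (%, vertical axes) taken by 8 ribosomal RNA-linked genes (left) and by the 13 mitochondrially encoded genes (right) in the control library (blue) and the OP-HU library (orange), over all cells and in each of 8 classes (horizontal axes). Error bars are exact 95% Poisson intervals of the summed UMIs over the total (counting error only). Over all cells the shares are 2.74% and 0.189% on the left and 0.196% and 0.710% on the right.

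The last comparison was of cell cycle genes. Of 52 measured G2 and M phase genes, 22 were higher and 5 lower in the OP-HU library (median 0.23, 0.10 to 0.43; percentile 98.4), led by Kif20b (1.32), Ccnb2 (1.20), Cenpe (1.15) and Hmmr (1.14). Of 43 S phase genes, 13 were higher and 2 lower (median 0.15, percentile 86.4), with Prim1 (1.13) and Gins2 (1.11) in front. The G2 and M list had a positive median in neutrophil progenitors (0.20), HSC and multipotent cells (0.30), monocyte progenitors (0.25), erythroid cells (0.15) and megakaryocyte cells (0.31). In late neutrophils it stood at -0.02, where the median over all genes was -0.20, at percentile 95.4 among random lists (93.7 in erythroid cells). Cell cycle inhibitors and quiescence genes had 8 of 22 higher and 5 lower (0.21), with Cish (1.16) and Cdkn1a (1.15) against Klf2. After each cell was thinned to 2000 UMIs, which left out 5851 control and 8637 OP-HU cells, phase calls placed 54.6% of control cells and 60.7% of OP-HU cells in G2 or M, and 44.3% and 38.2% in S. Only 1.12% and 1.07% were called G1. The calls therefore mainly split cells between S and G2 or M, and they are not read as the share of cells in cycle. Without thinning these shares were 53.2% and 58.0%, and 44.8% and 38.8%. Phase shares of a library sum to its cells, so the S share is not independent of the G2 and M share. Mean G2 and M scores were 0.261 (SD over cells 0.202) and 0.347 (0.230), and mean S scores 0.211 (0.198) and 0.223 (0.210). Phase calls and scores also read RNA free in the suspension, which was not measured here, so the part that it plays stays open and no rate of cycling is read from them. Median genes per cell at 2000 UMIs were 1281 and 1305, and 2257 and 2294 without thinning.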

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

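Of the tests given here, that on GC content and transcript length was written before its result was seen, and the others were chosen only after. Among the 28 lists of pathways and complexes, cell type markers not counted, 3 with at least 6 measured members moved in opposite directions in a pair of main classes, each with a median of at least 0.32 in size and outside the middle 95% of random lists on both sides. None of these differences was tested, since there is 1 library per condition. Myc targets and ribosome biogenesis genes had a median log2 ratio of 0.54 in erythroid cells and -0.54 in late neutrophils, a difference of 1.07 that was not tested. NF-kappaB and cytokine genes had 0.34 in late neutrophils and -0.53 in erythroid cells, a difference of 0.87 that was not tested. Immediate early genes had 0.43 in megakaryocyte cells and -0.46 in erythroid cells, a difference of 0.89 that was not tested. Markers of other cell types moved in the same classes: in erythroid cells primary granule markers had a median of -1.31 and monocyte markers -0.94, in late neutrophils early erythroid markers had 1.75, and 35.3% of the OP-HU megakaryocyte cells kept that class when labels were passed from the control library. Of the control late neutrophils, 75.8% kept that class when labels were passed from the OP-HU library.

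The erythroid share was 3.69-fold larger in the OP-HU library and the neutrophil progenitor share 2.37-fold smaller. The unequal UMI limits of the 2 libraries are argued against as the cause of the erythroid part, since its log2 ratio was 1.99 (1.94 to 2.04) with a common floor, as is the unequal removal of doublets, since it was 1.82 (1.77 to 1.86) with doublets kept. For neutrophil progenitors the common floor removed no control cell but renamed clusters (control progenitors from 50.1% to 37.3%, late neutrophils from 7.08% to 18.0%), and both classes together went from -0.95 to -1.09, which argues against the UMI limit there too. Loss of the removed doublets themselves is argued against as the whole cause, since counting every removed OP-HU cell and no removed control cell as neutrophil still left -0.52 (-0.54 to -0.50), but clustering with doublets kept gave -0.32 (-0.35 to -0.30) with 25.3% of control cells unnamed, so an effect of doublet removal through clustering and naming stays open. Red cell precursors that passed the CD117 selection more often in the OP-HU library remain open: counting early erythroid clusters alone left 1.49 (1.44 to 1.55), while Kit was lower in them (-0.75) and higher in the late clusters (0.63), which does not decide it, and a biological difference between the conditions also stays open and untested, because library and condition cannot be told apart.

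Brd4 was higher in the OP-HU library in 8 of 8 classes. The makeup of classes is argued against as the cause, since the log2 ratio was 0.63 with makeup held equal (0.61 to 0.64, with the width of the plain sums) and 0.44 to 0.71 in the classes. A trend on GC content (54.0% in the longest Brd4 transcript of 5957 nt, against medians of 49.2% and 3423.5 nt) is argued against too, since Brd4 stayed at 0.48 to 0.84 above it in each class, with 2.83% of the variance over all cells taken by the trend. A difference between the libraries that spreads the ratios of many genes may also be the source and cannot be told apart from a change of Brd4 itself, because its ratio lay at percentile 85.9 of the genes nearest in expression. A biological difference between the conditions stays open, as untested.

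The summed share of the 8 ribosomal RNA-linked genes was 14.5-fold lower in the OP-HU library. Gm42418 alone held 2.42% of control UMIs, out of 2.74% for the sum. Class makeup is argued against as the cause, since the log2 ratio lay between -4.54 and -3.45 in the classes compared. Reads from 1 source, such as ribosomal RNA fragments assigned to all of these genes, are a candidate source within the control library. Across its classes their ratios to Gm42418 varied with a median SD of 0.18 on the log2 scale, against 0.60 for genes matched on expression. AY036118 held to that ratio less closely (0.32), although its own level varied by 0.12. Between the libraries, log2 ratios over all cells were -5.56 for AY036118, -3.87 for Gm42418 and -2.61 for Gm26917. Loss of 1 source counted in fixed proportion would give all of these genes 1 ratio, which the values do not show. Whether the OP-HU library differed in ribosomal RNA capture, in its counting or in the cells was not tested.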

How the results depend on the processing

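The settings chosen only after the results were seen were the common UMI floor, the classes passed between libraries and the libraries clustered on their own, and the other settings were chosen before. No paired analysis was possible because each group has 1 library, and leaving out a replicate is not possible with 1 library per group for the same reason. The larger erythroid share (1.82 to 2.08 on the log2 scale) and the higher Brd4 level (0.60 to 0.69 over all cells) kept their direction in the alternatives run. The smaller neutrophil progenitor share also kept its direction but ranged from -1.36 to -0.28. Both neutrophil classes together, a sum added in every setting after the results were seen, ranged from -1.32 (thinned cells) to -0.03 (each library on its own, with 38.5% of control and 6.43% of OP-HU cells then unnamed). They stood at -0.32 with doublets kept, where 25.3% of control and 2.89% of OP-HU cells were unnamed, and at -0.61 with the looser filter (11.3% of control cells unnamed). Shares of late neutrophil and megakaryocyte cells changed direction. The cause was not tested for the values that moved or reversed here, except that a lower or higher CPM floor lets in more or fewer genes. A value counts as moved when it leaves the counting interval of the main value, and depth limits smaller classes more, through wider intervals. Among these, share ratios ranged from -0.08 to 0.62 for eosinophil cells (main 0.58), from 0.76 to 2.03 for basophil and mast cells (1.02), from -1.47 to -0.34 for the B lineage (-1.37), from 0.18 to 1.54 for dendritic cells (1.34) and from 1.73 to 3.57 for T, NK and innate lymphoid cells (3.44), over the settings that gave a value. The lowest eosinophil value came from the common floor, and the lowest dendritic and T cell values from classes passed from control.

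Log2 share ratios are given here in the order of main value and alternatives. For neutrophil progenitors (main -1.25) they were -1.32 at resolution 0.5, -1.12 at resolution 2, -1.31 with centred components, -1.15 with genes left out, -0.90 with thinned cells, -0.90 with the looser filter, -1.11 with the stricter filter, -0.68 with doublets kept, -0.92 with the common floor, -1.36 and -1.14 with classes passed from the OP-HU and from the control library, and -0.28 with each library on its own. For erythroid cells (main 1.88) they were 1.96 with genes left out, 2.08 thinned, 2.00 with the stricter filter, 1.82 with doublets kept, 1.99 with the common floor and 1.96 passed from control. For monocyte progenitors (main -0.26) they were -0.19 with genes left out, with doublets kept and with classes passed from either library, -0.028 thinned and -0.011 on its own. For HSC and multipotent cells (main 0.46) they were 0.77 and 0.83 at resolutions 0.5 and 2, 0.96 centred, 0.71 with genes left out, 0.74 thinned, 0.36 looser, 0.60 stricter, 0.88 with doublets kept, 0.74 with the common floor, and 0.84 and 0.74 passed from OP-HU and control. Libraries clustered on their own gave no value for that class. For late neutrophils (main 0.25) they were 0.62 and 0.18 at resolutions 0.5 and 2, 0.36 with genes left out, 0.73 with doublets kept, 0.65 passed from OP-HU and 0.91 on its own, and they reversed to -2.43 thinned, -1.14 stricter and -1.51 with the common floor. For megakaryocyte cells (main 1.46) they were 0.28 with genes left out, 0.44 thinned, 0.81 looser, 0.26 stricter, 1.07 with doublets kept and 0.80 passed from OP-HU, and they reversed to -0.091 at resolution 2, -0.27 centred, -0.24 with the common floor, -0.045 passed from control and -0.13 on its own. Cells took the class they had when labels were passed from OP-HU and from control in 98.2% and 94.7% (neutrophil progenitor), 98.1% and 99.2% (erythroid), 91.4% and 95.6% (monocyte), 71.3% and 85.6% (HSC), 75.8% and 98.5% (late neutrophil) and 99.6% and 35.3% (megakaryocyte) of cases.

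Brd4 over all cells (main 0.65) stood at 0.60 with TMM, 0.60 with totals without the abundant genes, 0.69 as a mean over cells, 0.63 with makeup held equal and 0.62 with makeup held equal over classes passed from OP-HU. Of 80 alternative values of Brd4 within classes, 67 stayed within the interval and 13 moved, between 0.39 and 0.77. Genes meeting the size rule (443 higher and 320 lower) numbered 433 and 193 as a mean over cells, a split of 69.2% higher against 58.1%, and 389 and 349 with TMM (52.7% higher). They numbered 176 and 105 with makeup held equal, 160 and 95 with makeup over classes passed from OP-HU, 177 and 86 passed from control, 808 and 598 at 1 CPM and 215 and 165 at 50 CPM. Of 220 values of the 20 genes named over all cells, 123 stayed, 97 moved and 0 reversed.

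Of 642 alternative values of 36 list medians, 547 stayed, 64 moved and 31 reversed. Values counted as stayed include changes of sign inside the interval over members, as for BET and transcription elongation genes (main 0.14, lowest -0.11). With makeup held equal, and again over classes passed from OP-HU and from control where these also left the interval, medians were 0.0037 and 0.076 for primary granule markers (main -0.76), -0.046 and -0.080 for basophil and mast markers (0.84), -0.13, -0.13 and -0.15 for late erythroid markers (1.80), -0.18, -0.22 and -0.18 for myeloid factors (-0.74), and -0.072, -0.076 and -0.090 for iron and haem genes (0.78), and 0.0055 over classes passed from OP-HU for glycolysis genes (-0.35). Within erythroid cells they were -0.43 for late granule markers (main 0.55), -0.71 for basophil and mast markers, -0.20 for early erythroid markers (2.05), -0.34 for late erythroid markers, -0.57 for BET-responsive genes (-0.27), -0.27 for leukaemia-associated stem genes (0.13), -1.23 for myeloid factors, 0.044 for glycolysis genes and -0.27 for iron and haem genes. Within late neutrophils they were 0.69 for megakaryocyte markers (-0.31), -0.056 for leukaemia-associated stem genes, 0.13 for myeloid factors, -0.54 for Myc targets (0.35), -0.015 for G2 and M genes (0.23), -0.27 for oxidative phosphorylation (0.39), -0.052 for iron and haem genes and -0.46 for ribosomal proteins (0.20). Within neutrophil progenitors they were 0.21 for primary granule markers, -0.19 for myeloid factors and -0.023 for Myc targets. Within monocyte progenitors they were -0.14 for late granule markers, -0.12 for myeloid factors and 0.017 for glycolysis genes. Within HSC and multipotent cells they were -0.12 for late granule markers and -0.52 for basophil and mast markers, and within megakaryocyte cells -0.077 for leukaemia-associated stem genes and 0.028 for glycolysis genes. The difference in S phase share (main -6.06 points) was -5.31 in neutrophil progenitors, -4.71 in erythroid cells, -9.66 in monocyte progenitors, -10.1 in HSC and multipotent cells, -8.57 in late neutrophils and -9.87 in megakaryocyte cells. That in G2 or M share (main 6.11) was 4.76 without thinning, and 4.99, 4.91, 9.45, 10.7 and 13.2 in neutrophil progenitor, erythroid, monocyte, HSC and megakaryocyte cells. In late neutrophils the difference in G2 or M share was 5.94 with thinning and reversed to -1.24 without. Thinning kept 2411 of 3150 control and 1730 of 3982 OP-HU late neutrophils, so phase shares of thinned cells leave out many cells of that class.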

Other observations

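No test of an explanation is reported in this part, and the classes and lists described were picked only after their values were seen. Many lists differed between the libraries within late neutrophils, where the median log2 ratio over all genes at 10 CPM or more was -0.20. All 17 measured late granule markers, which also gave the class its name, were higher in it (median log2 ratio 1.49, percentile 100 among random lists), while 12 of 16 primary granule markers were lower and 2 higher (-1.26). The ribosomal protein list, built from symbols, had 47 of 86 lower and 8 higher (-0.46, percentile 0.05). Myc targets had 18 of 28 lower and 1 higher (-0.54), S phase genes 24 of 43 lower and 3 higher (-0.43), and unfolded protein response genes 12 of 23 lower and 5 higher (-0.55). Quiescence genes had 13 of 21 higher and 0 lower (0.46), genes of p53 response and apoptosis 12 of 21 higher and 3 lower (0.64), and NF-kappaB and cytokine genes 12 of 24 higher and 3 lower (0.34). UMIs of other lineages were higher in this class as well: 16 of 17 early erythroid markers (median 1.75), 6 of 9 megakaryocyte markers (0.69) and 7 of 10 HSC markers (0.79), with haemoglobin UMIs 7.01-fold higher. Median depth in this class was 3427.5 UMIs in control and 1807.5 in OP-HU cells, and no background of free RNA was measured, so these are not read as expression by late neutrophils. Kit stood at 123 and 71.1 CPM in this class, and median genes per cell at 2000 UMIs were 1211 in control and 1059.5 in OP-HU cells. Thinning kept 2411 of 3150 control cells and 1730 of 3982 OP-HU cells of this class, so these medians leave out its shallower cells. Different clusters hold most of this class in the 2 libraries (cluster 11 against clusters 12 and 14), and its share reversed in some settings.

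Heat shock genes, the chaperones of protein folding, were higher in several classes, and differences between classes were not tested. In erythroid cells 12 of 13 were higher and 0 lower (median 0.65), in megakaryocyte cells 11 of 14 and 0 (0.66), and in basophil and mast cells 8 and 0 (0.55), with percentiles of 99.8 or more among random lists. HSC and multipotent cells (0.34, percentile 97.4), monocyte progenitors (0.21, 93.0), eosinophil cells (0.25, 93.8) and neutrophil progenitors (0.15, 83.1) lay inside the middle 95% of random lists. In late neutrophils the median was -0.19, at percentile 49.7 among random lists, so the list moved there as other genes of like expression did. MHC class I genes, which present peptides to T cells, had 0 of 11 higher and 8 lower in erythroid cells (-0.67, percentile 0). They stood at -0.36 in late neutrophils (percentile 22.4), -0.34 in eosinophil cells, -0.22 in basophil and mast cells, -0.19 in HSC and multipotent cells, -0.18 in monocyte progenitors, -0.09 in megakaryocyte cells and -0.01 in neutrophil progenitors. In erythroid cells interferon response genes had 11 of 15 lower and 0 higher (-0.77), and niche adhesion and migration genes 12 of 16 lower and 0 higher (-0.62). Leukocyte markers were lower in the same cells: 16 of 16 primary granule markers (-1.31), 7 of 10 monocyte markers (-0.94) and 17 of 19 myeloid factors (-1.23). Of the OP-HU megakaryocyte cells, 35.3% kept that class when labels were passed from the control library. Clusters named late erythroid make up 6.85% of the erythroid cells of the control library and 29.0% of those of the OP-HU library, and these lists were not compared within stages. In the erythroid class, however, haemoglobin genes took 0.240% of control UMIs and 0.184% of OP-HU UMIs. Late erythroid markers had a median of -0.34 there, so the cluster names may not mark the same stage in both libraries.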
